A study of Mus musculus with 22 samples.

How the data were processed

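Total RNA of sorted thymocytes was isolated with RNeasy mini kits and made into libraries with the NuGEN Ovation Ultralow system, per the labels' protocols. The authors deposited FPKM values (fragments per kilobase of gene, scaled to sequencing depth) per gene in 3 tables, of the Vav groups at 4 weeks, the Lck groups at 4 weeks, and the 8-week groups with the transplanted mice. Per the submitters' processing notes, Trimmomatic 0.33, STAR, HTSeq 0.6.1 and DESeq2 were named with the genome build mm10, without a role or order. Which gene lengths and annotation entered the FPKM, and whether counting used strand, is not given in the sources used here. Overlapping and antisense genes can therefore not be told apart, and gene families with near-identical members, such as receptor segments, are uncertain one by one.

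Each table held 43430 genes by Ensembl identifier, of which 42462 were matched to a symbol of the GENCODE annotation of the same build. That annotation gave chromosome, start, end and strand. The columns were matched to samples by their names, and 0 columns of sample values were left unused. No pair among the 22 libraries was identical (0 pairs), and the highest correlation between libraries was 0.99681. In FPKM, 1 read has a value set by gene length and depth, so the read totals were inferred from the lowest values. They lay between 5.49 and 37.5 M reads, where M stands for 1e6. Between 50.1% and 57.3% of the low values were whole multiples of a read within a tolerance of 0.03, too few to recover read counts, so no count model was used. The tests planned for raw counts had no counts to run on. FPKM summed to between 198963 and 250725 per library.

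Values were tested as log2(FPKM + 1) with limma 3.58.1 (trend) in R 4.3.3. Fold changes are on that scale, which understates changes of low genes. Genes needed 1 FPKM or more in at least 3 libraries of each table in the fit. An adjusted p (Benjamini-Hochberg) under 0.05 was called. The 4-week comparisons used the 6 libraries of their table. The 8-week comparisons used 1 fit of the 10 libraries of their table. The differences of effects used 12 libraries as an interaction, in which an offset of a gene between tables cancels. Tables were treated as separately normalized, so no gene was tested between tables directly. Values of several tables stand side by side only as descriptions.

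Before the data were examined, 25 gene lists were fixed for the T cell lineage, other cell types and cell states. They cover E proteins, Notch, the double-positive stage, early progenitors, T cell receptor response, mature T cells, cell cycle, ribosome biogenesis, interferon response, p53, BCL2, leukaemia, glycolysis, oxidative phosphorylation, trafficking, innate-like and gamma-delta cells, B cell, macrophage, dendritic, stromal and erythroid markers, immediate early and heat shock, mitochondrial and sex-linked genes. Lists with at least 3 tested members went into limma's camera with a preset correlation of 0.01, adjusted over lists. An estimated correlation and fry were the alternatives. The counts adjusted over the list alone used that list's genes only.

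The rule for named genes was also fixed then. It takes Tcf3, the 8 largest rises and 8 largest falls of each comparison among called genes whose libraries do not overlap (4 each way for transplanted against control, 5 each way for the differences of effects), up to 4 called members of each list that was called or had 3 called members, and the 5 smallest p each way where no gene passed. Predicted genes, pseudogenes and receptor segments were left out of the largest changes.

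Overlaps of calls used Fisher's exact test in both directions over genes tested in both comparisons. Where comparisons shared libraries, 100 simulations of unchanged groups gave the correlation that sharing produces. Chromosome medians used genes with a mean of 5 FPKM or more in the controls, relative to the library's median over autosomes, with a control library compared with the other controls. The sex of a library was inferred from Xist and Ddx3y.

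The model was tested on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale. The changed genes were drawn from the more highly expressed of the tested genes, with independent noise for each gene. Recovery among lower genes was not measured. At 4 weeks 91 and 98 were recovered for Vav (10828 genes) and 91 and 98 for Lck (10946 genes). At 8 weeks 50 and 89 were recovered for knockout against control and 67 and 87 for transplanted against control (11632 genes). The differences of effects recovered 89 and 95 (Vav against Lck, 10541 genes) and 83 and 97 (8 against 4 weeks, 10489 genes). The median standard error was 0.0849 at 4 weeks and 0.216 at 8 weeks for the Vav knockout, so smaller changes could be called at 4 weeks.

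Alternatives fixed beforehand were a pseudocount of 0.1, no filter or a mean of 5 FPKM, scaling to a common sum, median-of-ratios and quantile scaling, robust variances, array weights, a replicate block, fits with more or fewer groups and each replicate left out. Robust variances applied to genes only, and array weights to genes and to lists in camera. Others were added after the data were seen. They left out genes on X and Y, on chromosome 15 or of receptor segments, centred chromosome 15, or added inferred sex as a covariate. Figures and summaries used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.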

Results

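RNA was sequenced from CD45.1+ CD4+CD8+ thymocytes, the double-positive stage of T cell development, of mice with or without a deletion of E2a. The gene symbol of E2a is Tcf3, and its products are E proteins, transcription factors that direct lymphocyte development. The deletion was driven by Cre recombinase from Vav, active across blood cell lineages, or from Lck, active in developing T cells. There were 22 libraries in 7 groups: 3 Vav controls and 3 Vav knockouts at 4 weeks of age, 3 Lck controls and 3 Lck knockouts at 4 weeks, 3 Vav controls and 3 Vav knockouts at 8 weeks, and 4 transplanted Vav knockouts at 8 weeks. Controls carried the floxed E2a alleles, with no Cre named in their genotype. The transplanted mice were sublethally irradiated, received wild-type bone marrow as competitor cells and were analysed 4 weeks later. Which cells of those mice carried CD45.1 is not stated in the labels. The values were FPKM in 3 tables, and the low values implied between 5.49 (Lck knockout replicate 2) and 37.5 (Vav control replicate 3 at 4 weeks) M reads per library, where M stands for 1e6. The labels call the libraries replicates without naming the animals, so p-values measure the spread between these libraries.

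Tcf3 (ENSMUSG00000020167, mm10 chromosome 10, 80409514 to 80433647, minus strand) was lower in every knockout library than in every control library of the same table. At 4 weeks the Vav controls had 7.47, 6.39 and 6.73 FPKM and the Vav knockouts 1.36, 1.39 and 1.15 FPKM. The Lck controls had 7.50, 8.22 and 6.98 FPKM, and the Lck knockouts 1.33, 1.2 and 1.2 FPKM. At 8 weeks the controls had 7.59, 7.52 and 7.49 FPKM, the Vav knockouts 2.13, 1.23 and 2.01 FPKM, and the transplanted Vav knockouts 1.22, 1.31, 2.32 and 1.21 FPKM. The log2 fold change against control was -1.77 (SE 0.0798, adjusted p = 0.000363) for Vav at 4 weeks, -1.93 (SE 0.0724, adjusted p = 0.000608) for Lck, -1.63 (SE 0.194, adjusted p = 0.00165) for Vav at 8 weeks and -1.79 (SE 0.181, adjusted p = 0.000548) after transplantation. Gene-level values do not show which exons the remaining reads came from.

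**Figure D1:**
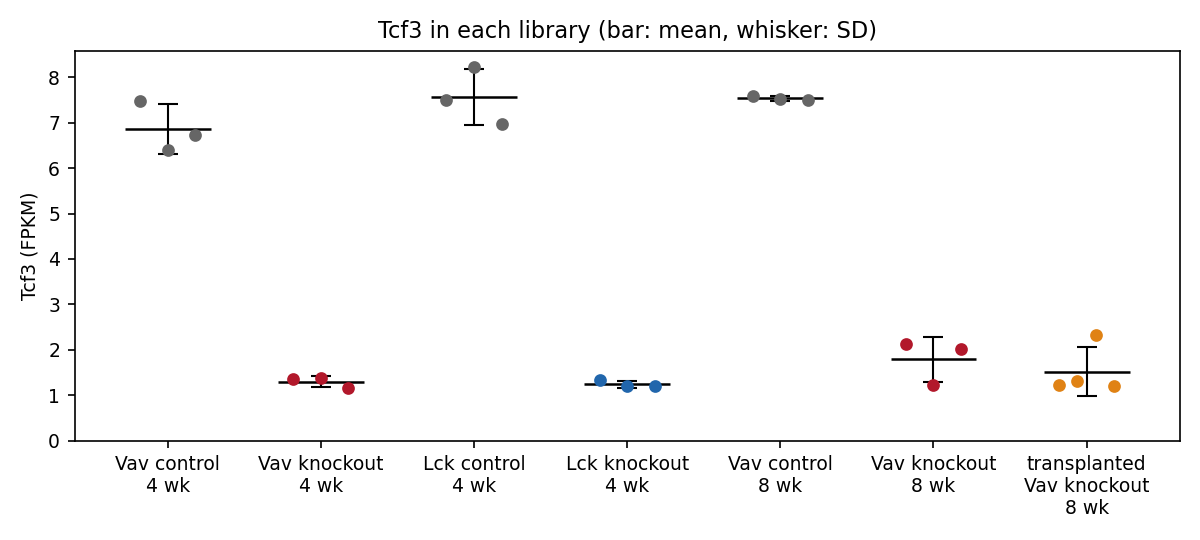
Tcf3 in FPKM (vertical axis) in each of the 22 libraries (points), by group (horizontal axis), with the group mean (bar) and SD (whisker). The highest knockout library of the 8-week table, transplanted replicate 3 at 2.32 FPKM, lies below the lowest control library of that table at 7.49 FPKM.

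The first comparison asked what loss of E2a in all blood cells had done to double-positive thymocytes by 4 weeks. Most tested genes of the Notch pathway, of mature T cells and of the interferon response rose. Dtx1, a Notch target, rose from 1.38 ± 0.274 to 18.2 ± 6.59 FPKM (SD, n = 3 each), a log2 change of 2.95. Il2ra, the interleukin-2 receptor alpha chain of earlier thymocytes, rose from 1.96 ± 0.154 to 23.1 ± 8.86 FPKM (2.95). Sdc1, a cell surface proteoglycan, went from 0.245 ± 0.0594 to 11.5 ± 4.73 FPKM (3.26), Itgb7, an integrin chain, from 3.81 ± 0.531 to 29.5 ± 4.09 FPKM (2.66), and Ly6d, a lymphoid progenitor surface antigen, from 78.3 ± 10.3 to 485 ± 55.4 FPKM (2.62). Fbln1 (2.63), Cd163l1 (2.32) and Scara3 (2.27) were the other large rises. The largest falls were Dhrs3 (-2.58), a retinal reductase, Epha2 (-2.53), a receptor tyrosine kinase, Cd79b (-2.37), part of the B cell receptor, H1fx (-2.36), a linker histone, Fgf13 (-2.34), Car2 (-2.33), a carbonic anhydrase, Smim3 (-2.10) and Arap2 (-1.93).

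Of 9 Notch pathway and target genes, 6 rose, 2 fell and 1 did not pass, with the same counts adjusted over the list alone. Ptcra (-1.21), the pre-T cell receptor alpha chain, and Igf1r (-0.69) were the falls, both named after their values were seen. Il2ra, Dtx1, Myc (1.51), the growth-promoting transcription factor, and Notch1 (1.43) led the list, whose camera test gave an adjusted p of 0.00556 (adjusted p = 0.444 with an estimated correlation). Of 17 double-positive stage and recombination genes, 6 fell, 2 rose and 9 did not pass (8 fell and 2 rose adjusted over the list alone). Plxnd1 (-1.26), Rag2 (-0.61), a subunit of the receptor gene recombinase, and Arpp21 (-0.54) fell, while Aqp11 (0.55) rose, and the list was lower (adjusted p = 0.00289, adjusted p = 0.444 with an estimated correlation). Of 8 genes of mature single-positive T cells, 7 rose and 1 did not pass, as also when adjusted over the list alone. They included Gimap3 (1.68), Klf2 (1.52), a regulator of thymic exit, Il7r (1.47) and Runx3 (1.24), and the list was higher (adjusted p = 4.76e-07, adjusted p = 0.0969 with an estimated correlation). Of 13 interferon-stimulated genes, 10 rose and 3 did not pass (11 rose adjusted over the list alone), with Ifi27l2a at 1.26, Rtp4 at 1.23, Zbp1 at 0.91 and Isg15 at 0.83 (adjusted p = 4.62e-08, adjusted p = 0.114 with an estimated correlation).

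Of 22 ribosome biogenesis genes and MYC targets, 16 rose and 6 did not pass (21 rose adjusted over the list alone), among them Srm (1.09), Rrp12 (0.73), Polr1b (0.68) and Cad (0.67). Their adjusted p was 1.33e-11 (adjusted p = 0.327 with an estimated correlation). Of 9 trafficking receptors 5 rose and 4 did not pass, in the list alone as well, with S1pr1 at 0.99 and Ccr7 at 0.64 among them (adjusted p = 0.00364, adjusted p = 0.148 with an estimated correlation). Of 5 innate-like and cytotoxic T cell genes 4 rose (5 adjusted over the list alone), namely Il2rb (0.93), Nkg7 (0.85), Icos (0.80) and Id2 (0.54), with an adjusted p of 5.77e-05 (adjusted p = 0.148 with an estimated correlation). Of 4 gamma-delta T cell genes 3 rose (4 adjusted over the list alone): Tcrg-C2 (3.02), Cd163l1 and Tcrg-C4 (2.04), with an adjusted p of 0.000397 (adjusted p = 0.297 with an estimated correlation). The constant segments of that locus are near-copies of each other, so their single values are uncertain. Of 10 mitochondrially encoded genes 3 rose (4 adjusted over the list alone), mt-Nd6 by 0.42, mt-Nd5 by 0.35 and mt-Atp6 by 0.32 (adjusted p = 0.00283, adjusted p = 0.444 with an estimated correlation). Of 23 oxidative phosphorylation genes only Ndufb9 (0.51) and Cox5a (0.36) rose, 1 of them adjusted over the list alone (adjusted p = 0.00326, adjusted p = 0.444 with an estimated correlation). Among 6 genes of the E protein and Id family, Id1 (0.74) and Id2 rose, Tcf3, Id3 (-0.63) and Tcf4 (-0.35, named after its value was seen) fell and 1 did not pass, in the list alone as well. The set had an adjusted p of 0.486, and 0.0483 without knockout replicate 2.

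Other lists were not called at 4 weeks. Of 17 genes of the T cell receptor response Cd53 (1.49), a tetraspanin, rose with 1 more, Cd5 (-0.88), Cd6 (-0.65) and Id3 fell, and 12 did not pass, also adjusted over the list alone (adjusted p = 0.187). Of 19 genes altered in T cell leukaemia 6 rose and 13 did not pass, Myc, Il7r, Notch1 and Notch3 (1.23) among the rises (6 rose and 1 fell adjusted over the list alone). That list had an adjusted p of 0.189, a mean of 0.29 and a median of -0.03. Of 40 cell cycle genes 1 rose (0 adjusted over the list alone, adjusted p = 0.663), and of 14 p53 targets 1 rose (0 adjusted over the list alone, adjusted p = 0.476). In the BCL2 family 1 of 11 rose, in the list alone as well (adjusted p = 0.663), with a median of 0.07 and a mean of -0.0071. Of 15 glycolysis genes 2 fell, in the list alone as well (adjusted p = 0.495), with a median of 0.0064 and a mean of -0.05. Of 6 immediate early and heat shock genes 1 rose (2 adjusted over the list alone, adjusted p = 0.396), and of 3 thymic stroma markers 1 rose and 1 fell (2 and 1 adjusted over the list alone, adjusted p = 0.772, and 0.0409 without control replicate 1). The other marker lists had fewer than 3 measurable members and no list test. Cd79b of the B cell markers fell, H2-Ab1 (0.97) of the dendritic cell markers, Itgam (0.90) of the macrophage and granulocyte markers and Il2ra of the early progenitor genes rose, and no erythroid or sex-linked gene passed. H2-Ab1 and Itgam were named after their values were seen. Adjusted over the list alone, 2 B cell markers fell, and the other counts were unaltered.

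In limma's test, 826 of 10828 genes were higher and 658 lower in the Vav knockout at 4 weeks, 120 and 119 of them by a log2 change of 1 or more. The libraries of the groups did not overlap at 37.8% of genes, against 10% by chance. Of the 812 autosomal genes called higher, 148 lay on chromosome 15 (18.2%, against 4.03% of the tested genes), Myc, Itgb7, Ly6d, Fbln1, Il7r, Il2rb and Ndufb9 among them, and 645 higher and 625 lower calls were left without that chromosome. Leaving out control replicate 1, 2 or 3 lowered the counts to 391 and 225, 303 and 187, and 323 and 203, and leaving out knockout replicate 3 gave 411 and 391. Scaling each library to the same sum made 613 higher and 981 lower, or 38.5% higher in place of 55.7%.

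**Figure D2:**
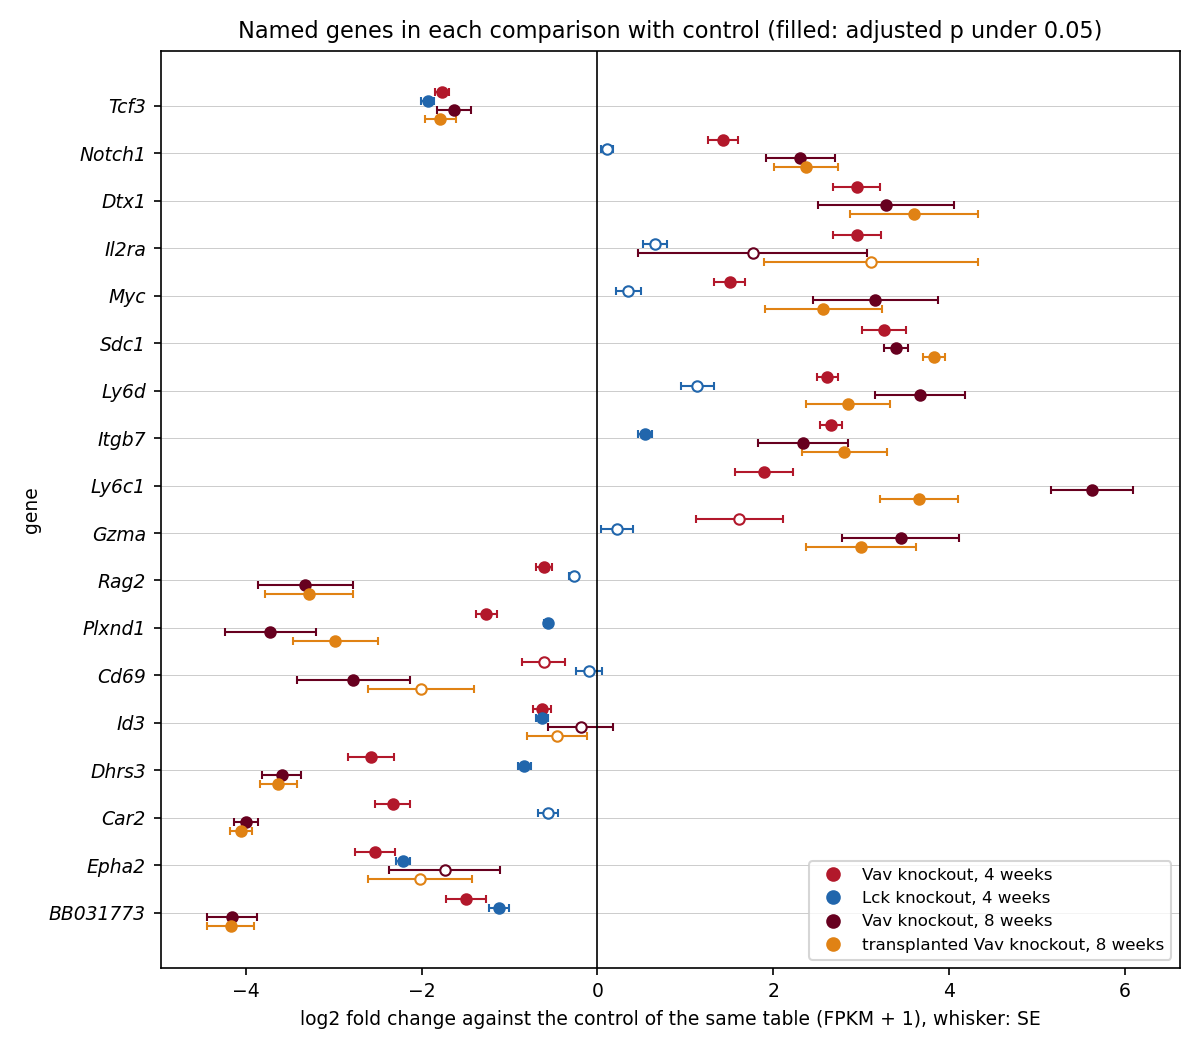
The log2 fold change (horizontal axis, FPKM + 1, whisker SE) of 18 named genes (vertical axis) against the controls of the same table, for the 4 knockout groups (colours). Filled points have an adjusted p under 0.05, such as Epha2 at -2.53 in the Vav and -2.21 in the Lck knockout at 4 weeks, and a missing point means that the gene was not tested in that comparison.

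The second comparison asked the same of a deletion that began within the T cell lineage. Few genes were called in the Lck knockout, and the called falls were larger than the rises. Epha2 fell from 15.1 ± 0.948 to 2.48 ± 0.294 FPKM (SD, n = 3 each), a log2 change of -2.21. Slc5a9, a sugar transporter, fell from 18.8 ± 0.908 to 6.66 ± 1.17 FPKM (-1.38), Smoc1 from 9.13 ± 0.990 to 2.98 ± 0.908 FPKM (-1.37) and BB031773 from 29.7 ± 1.64 to 13.2 ± 2.17 FPKM (-1.12). Ccdc153 (-1.04) and Mir7211 (listed at 0 in all 3 knockout libraries) were among the other large falls after Tcf3. Mir7211 lies on chromosome 10, as Tcf3 does. The largest rises were Reep1 (0.83), Cyth4 (0.80), Tmem173 (0.64), the innate DNA-sensing adaptor STING, Tpm4 (0.63), Sept8 (0.61), Itgb7 (0.54), Chd3 (0.48) and Emp3 (0.48).

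Of 5 E protein and Id genes, Tcf3 and Id3 (-0.63) fell and 3 did not pass, also adjusted over the list alone (adjusted p = 5.94e-05, adjusted p = 0.105 with an estimated correlation). Of 17 double-positive stage genes, Plxnd1 (-0.57) fell and 16 did not pass (7 fell adjusted over the list alone), and the list was lower (adjusted p = 0.000154, adjusted p = 0.105 with an estimated correlation). No cell cycle gene of 40 passed in limma's test over all genes, while 24 were higher and 1 lower adjusted over the list alone. Their fold changes were positive for 37 of 40 with a median of 0.18, and the list was higher (adjusted p = 2.53e-12, adjusted p = 0.149 with an estimated correlation, adjusted p = 0.0079 with fry). Of 22 ribosome biogenesis genes none passed over all genes and 2 rose adjusted over the list alone (adjusted p = 1.38e-05, adjusted p = 0.227 with an estimated correlation). Of 3 B cell markers only Igkc (-2.34) fell, from 4.47 ± 1.12 to 0.0679 ± 0.118 FPKM (1 adjusted over the list alone, adjusted p = 0.000729, adjusted p = 0.216 with an estimated correlation), and that call was lost without control replicate 1 (adjusted p = 0.178) or 3 (adjusted p = 0.249). The Notch list was not called (1 of 8 fell and 7 did not pass, 1 rose and 1 fell adjusted over the list alone, adjusted p = 0.347). Nor were the T cell receptor response (2 of 16 fell, 0 rose, adjusted p = 0.364), trafficking (2 of 8 rose, 0 fell, adjusted p = 0.281) and mature T cell lists (1 of 7 rose, 0 fell, adjusted p = 0.446). With single libraries left out, the oxidative phosphorylation and the immediate early and heat shock lists were called higher. The mitochondrially encoded and sex-linked lists were then called lower (adjusted p from 0.0142 to 0.0411 for these lists).

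In limma's test, 22 of 10946 genes were higher and 88 lower, 0 and 11 of them by a log2 change of 1 or more. An unadjusted p under 0.05 went to 1503 genes where 547 would be met by chance, so more genes may have changed than were called. Groups did not overlap at 20% of genes, against 10% by chance, and 3 of the 22 genes called higher lay on chromosome 15. These counts rested on every library: they were 0 and 2, 1 and 15, and 1 and 4 without control replicate 1, 2 or 3, and 11 and 72, 1 and 23, and 1 and 31 without knockout replicate 1, 2 or 3. Scaling to the same sum gave 5 higher and 85 lower (5.56% higher in place of 20%), and a term for sex inferred from expression left 1 and 25. By Xist and Ddx3y all 3 controls and knockout replicates 1 and 2 were male, and knockout replicate 3 female. The term for sex therefore only set that 1 library apart, much as leaving it out did, and does not measure sex. Gm23935, singled out after its values were seen, was at 844, 22948.7 and 18533.5 FPKM in the knockouts and 1364.7 to 8133.88 FPKM in the controls. The 10 most abundant genes took 8.02%, 16.6% and 14.2% of all FPKM in the knockouts and 7.65% to 10.4% in the controls.

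The difference between the Vav and Lck effects at 4 weeks was tested directly, as an interaction across both tables. The Vav effect was more positive for Il2ra by 2.30 (SE 0.335), Itgb7 by 2.12 (SE 0.159), Foxb1 by 2.48 (SE 0.400), Phlda1 by 2.03 (SE 0.318) and Mir7211 by 3.32 (SE 0.370). It was more negative for H1fx (-2.67, SE 0.407), Fgf13 (-2.22, SE 0.0978), Mir378b (-2.07, SE 0.442), Cd79b (-2.04, SE 0.203) and Laptm4b (-1.91, SE 0.221). Of 13 interferon-stimulated genes 6 had a higher Vav effect and 7 did not pass (10 adjusted over the list alone), and of 6 mature T cell genes 3 did (4 adjusted over the list alone). The interferon list had an adjusted p of 5.67e-11 (adjusted p = 0.00984 with an estimated correlation) and the mature T cell list one of 1.92e-07 (adjusted p = 0.0202 with an estimated correlation). The Notch list had 4 of 8 genes with a higher Vav effect (5 higher and 2 lower adjusted over the list alone, adjusted p = 0.00322, adjusted p = 0.329 with an estimated correlation). The ribosome biogenesis list had 1 of 22 (14 adjusted over the list alone, adjusted p = 2.87e-12, adjusted p = 0.143 with an estimated correlation). Tcf3 itself differed by 0.16 (adjusted p = 0.513).

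In limma's test of the interaction, 174 of 10541 genes had a higher and 174 a lower Vav effect. Genes had to pass the filter in both tables. Of the 120 Vav rises of a log2 change of 1 or more only 66 did, against 117 of 119 such falls. Sdc1 and Dtx1 were among the rises left out, so the balance and the largest differences hold for the tested genes only. Without the filter 241 were higher and 189 lower. Of the 173 autosomal higher calls 59 lay on chromosome 15 (34.1%, against 3.98% of tested genes), Itgb7 among them, and 102 higher and 151 lower were called without it. Counts were 111 and 85, 75 and 53, and 80 and 53 without Vav control replicate 1, 2 or 3, 96 and 104, 119 and 113, and 114 and 109 without Lck control replicate 1, 2 or 3, 224 and 265 without Vav knockout replicate 2 and 109 and 106 without Lck knockout replicate 2. Both effects still shared genes: of the 85 Lck falls tested in both, 65 were also Vav falls, where 5.25 would be shared by independent lists (Fisher's exact test, p = 5.01e-62), and 15 of 22 Lck rises were Vav rises against 1.52 (Fisher's exact test, p = 3.58e-13). Another 2 genes that rose in the Vav knockout fell in the Lck knockout. Across genes, which are not independent replicates, the fold changes correlated with Pearson's r = 0.359 and Spearman's rho = 0.385.

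The third comparison took the Vav deletion to 8 weeks. Ly6c1, a surface antigen of memory T cells, rose from 0.127 ± 0.0458 to 56.5 ± 17.6 FPKM (SD, n = 3 each), a log2 change of 5.63. Igf2bp3, an RNA-binding protein of fetal tissues, rose from 0.324 ± 0.0525 to 18.1 ± 1.97 FPKM (3.85), Gzma, the cytotoxic protease granzyme A, from 33.6 ± 5.83 to 381 ± 87.4 FPKM (3.45), and the heat shock genes Hspa1b and Hspa1a, near-identical copies whose single values are uncertain, by 4.81 and 3.96. Fbln1 (3.88), Ly6d (3.67) and Sdc1 (3.40) rose as at 4 weeks. Rag2 fell from 61.3 ± 1.78 to 5.25 ± 0.698 FPKM (-3.32), Plxnd1 from 204 ± 6.17 to 15.2 ± 6.07 FPKM (-3.72) and Car2 from 16.3 ± 0.766 to 0.0887 ± 0.136 FPKM (-4.00). Arl5c (-4.18), BB031773 (-4.16), Arap2 (-3.69), Dhrs3 (-3.59) and Gabarapl1 (-3.20) were the other large falls.

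Of 12 Notch pathway and target genes 6 rose and 6 did not pass (7 adjusted over the list alone). Dtx1 (3.29), Myc (3.16), Heyl (2.41) and Notch1 (2.31) led, with an adjusted p of 0.00599 (adjusted p = 0.445 with an estimated correlation). Of 17 double-positive stage genes Plxnd1, Rag2 and Rag1 (-1.45) fell and 14 did not pass (6 fell and 1 rose adjusted over the list alone, adjusted p = 0.00603, adjusted p = 0.539 with an estimated correlation). Of 18 genes of the T cell receptor response 5 fell and 13 did not pass (6 adjusted over the list alone), among them Cd69 (-2.78), an activation antigen, Egr3 (-1.5), Cd6 (-1.18) and Bcl2 (-1.05), with an adjusted p of 0.0156 (adjusted p = 0.539 with an estimated correlation). Of 22 ribosome biogenesis genes 5 rose and 17 did not pass (20 adjusted over the list alone), led by Polr1b (1.73), Mybbp1a (1.68), Gnl3 (1.53) and Wdr43 (1.21), with an adjusted p of 6.99e-09 (adjusted p = 0.51 with an estimated correlation). Of 10 mitochondrially encoded genes 6 rose (10 adjusted over the list alone), mt-Nd6 from 258 ± 16.7 to 832 ± 40.2 FPKM (adjusted p = 4.46e-08, adjusted p = 0.445 with an estimated correlation). Of 10 immediate early and heat shock genes 4 rose and 6 did not pass, also in the list alone, with Fos at 3.18 and Junb at 1.15 beside the Hspa1 pair (adjusted p = 0.00603, adjusted p = 0.445 with an estimated correlation). Of 23 oxidative phosphorylation genes only Ndufb9 (1.15) rose, in the list alone as well (adjusted p = 0.0136, adjusted p = 0.659 with an estimated correlation). Of 3 B cell markers Cd79b (-2.71) and Ighm (-0.87) fell, in the list alone as well (adjusted p = 0.0156, adjusted p = 0.445 with an estimated correlation, and adjusted p = 0.062 without transplanted replicate 3).

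Other lists were not called at 8 weeks. None of 11 mature T cell genes passed, over all genes or over the list alone (adjusted p = 0.21). Of 10 trafficking receptors only Itgb7 (2.34) rose, and of 6 innate-like genes only Gzma, in the lists alone as well (adjusted p = 0.948 and 0.164). In the T cell leukaemia list 4 of 20 genes rose (6 rose and 1 fell adjusted over the list alone), Myc, Notch1, Notch3 (1.64) and Cdkn2a (1.07), with an adjusted p of 0.136, and 0.0317 without knockout replicate 3. Of 40 cell cycle genes none passed, over all genes or over the list alone (adjusted p = 0.558), with a median of -0.02 and a mean of 0.13. With a term for sex the list was called higher (adjusted p = 0.00793). No interferon-stimulated gene of 15 passed either way (adjusted p = 0.225). None of 16 glycolysis genes passed either way (adjusted p = 0.242, and 0.0182 with a term for sex). Nor did any of 4 gamma-delta T cell genes, over all genes or over the list alone (adjusted p = 0.206, and 0.0182 with a term for sex). None of 3 erythroid markers passed over all genes or over the list alone (adjusted p = 0.136, 0.034 without control replicate 2 and 0.0352 without knockout replicate 1). None of 3 macrophage and granulocyte markers passed either (adjusted p = 0.252), and 1 of 3 dendritic cell markers rose, in the list alone as well (adjusted p = 0.252). Of 5 sex-linked genes none passed over all genes, while 4 were higher and 1 lower adjusted over the list alone (adjusted p = 0.157). Yet Xist was at 101 to 117 FPKM in the 3 controls and 0.00283 to 0.00743 FPKM in the 3 knockouts. The fit took its spread also from the transplanted libraries, of both sexes, where Xist ran from 0.00262 to 185 FPKM. Limma gave an unadjusted p under 0.05 to 3417 genes in all.

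In limma's test, 541 of 11632 genes were higher and 518 lower at 8 weeks, 289 and 279 of them by a log2 change of 1 or more, and groups did not overlap at 57.6% of genes against 10% by chance. Of 523 autosomal higher calls 146 (27.9%, against 4.13% of tested genes) lay on chromosome 15, with Ly6c1, Ly6d, Fbln1, Myc and Ndufb9 among them, and 353 higher and 471 lower remained to be called without it. The spread was shared with the transplanted libraries, so the counts moved with them: 1903 and 1632 without transplanted replicate 3, 2511 and 2494 from the 6 control and knockout libraries alone, and 2879 and 2886 with array weights. Without control replicate 1, 2 or 3 they were 92 and 73, 76 and 66, and 102 and 69, and without knockout replicate 1, 2 or 3 they were 189 and 213, 234 and 248, and 173 and 208. By Xist and Ddx3y the 3 controls were female and the 3 knockouts male. A term for sex, which only the transplanted libraries could inform, gave 1545 and 1294. Transplanted replicates 3 and 4 were the males there. For counts and lists alike, the term can therefore not be separated from what set replicate 3 apart. Scaling to the same sum moved the median of all genes to -0.14.

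Genes of chromosome 15 were higher as a set in each of the 10 Vav knockout libraries, a measure chosen after the gene calls were seen. Their median log2 difference from the controls, relative to the library's median over autosomes, was 0.288, 0.25 and 0.3 at 4 weeks, 0.707, 0.559 and 0.645 at 8 weeks, and 0.531, 0.566, 0.509 and 0.557 after transplantation. In the Lck knockouts it was 0.0175, 0.0260 and -0.00396. No control library exceeded 0.0195 in either direction. On other autosomes the controls lay between -0.0267 and 0.0286. Chromosome 6 was below that range in all 10 Vav knockout libraries, at -0.0452, -0.0425 and -0.0463 at 4 weeks, -0.0713, -0.0813 and -0.107 at 8 weeks, and -0.0471, -0.0876, -0.0465 and -0.0334 after transplantation. Chromosome 18 was at 0.0842, 0.0975 and 0.196 at 8 weeks, 0.00527, 0.102, 0.00847 and 0.0565 after transplantation, and 0.00851, 0.135 and -0.0255 at 4 weeks. Single libraries stood out with chromosome 10 at 0.376 in Vav knockout replicate 3 at 8 weeks and chromosome 8 at 0.417 in transplanted replicate 1. Among smaller shifts were 0.1 and 0.136 on chromosomes 10 and 13 in Vav knockout replicate 2 at 4 weeks, 0.0979, 0.126 and 0.12 on chromosomes 1, 2 and 4 in replicate 3 of that age, -0.101 on chromosome 17 in transplanted replicate 1 and -0.111 on chromosome 19 in transplanted replicate 3.

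**Figure D3:**
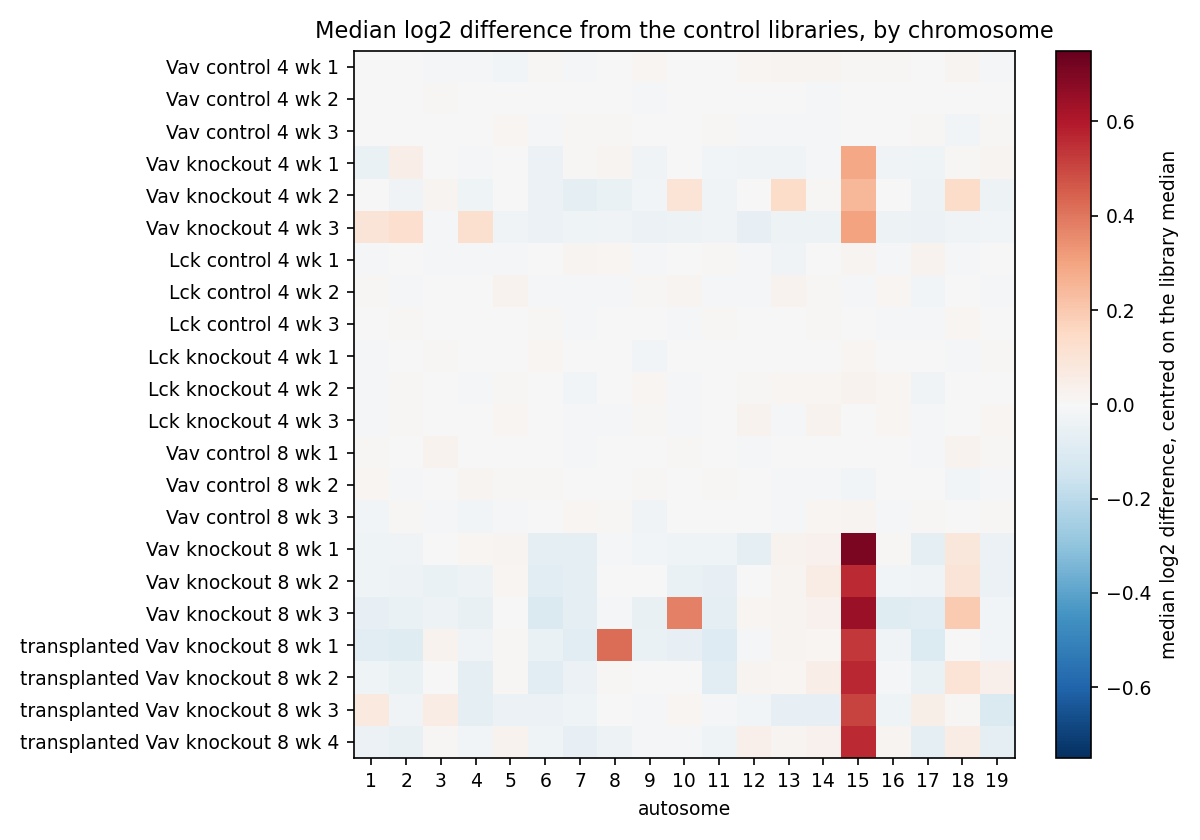
Median log2 difference from the controls of the same table (colour) for each autosome (horizontal axis) in each of the 22 libraries (vertical axis), relative to the library's median over autosomes. Chromosome 15 reaches 0.707 in Vav knockout replicate 1 at 8 weeks and stays within 0.0260 of 0 in the Lck knockouts.

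The use of T cell receptor beta variable segments was narrower in the Vav knockouts. The leading segment took between 16.5% and 20.7% of their summed FPKM in the 9 control libraries and 19.6%, 20.4% and 20.5% in the Lck knockouts. It took 21.9%, 49.3% and 48.1% in the Vav knockouts at 4 weeks, and at 8 weeks 78.2% (Trbv1), 66.9% (Trbv29) and 55.5% (Trbv2). After transplantation it took 98.0% (Trbv2), 92.4% (Trbv26), 65.1% (Trbv2) and 28.3% (Trbv3), the last in a library whose beta variable segments summed to only 26.9 FPKM. They summed to 196.8 FPKM in Vav knockout replicate 2 at 8 weeks, 1718 and 2460 FPKM in the other knockouts of that age and between 2073 and 2194 FPKM in their controls. This measure was also chosen after the calls were seen. Related segments can share reads, so single shares are uncertain. The summed constant segments of the gamma receptor were between 2.37 and 7.85 FPKM in the controls, 8.89, 3.93 and 5.94 FPKM in the Lck knockouts, 25.8, 76.1 and 34.8 FPKM in the Vav knockouts at 4 weeks, 178, 10.2 and 51.7 FPKM in those at 8 weeks, and 756, 840, 34.4 and 16.5 FPKM after transplantation.

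**Figure D4:**
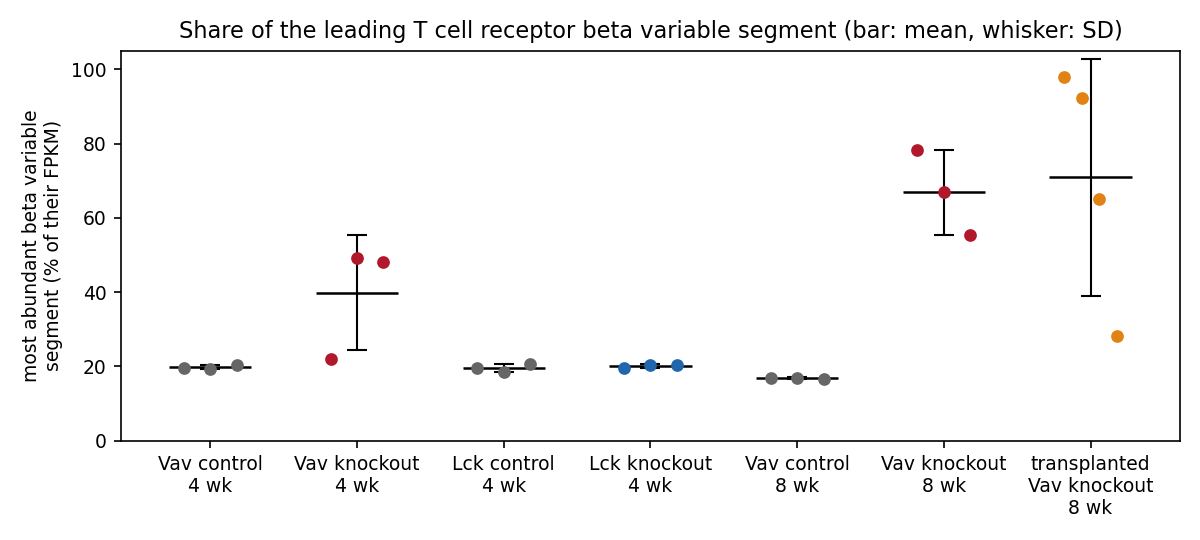
Share of the most abundant beta variable segment in the summed FPKM of all beta variable segments (vertical axis, percent) in each of the 22 libraries (points), by group (horizontal axis), with mean (bar) and SD (whisker). The 9 controls lie between 16.5% and 20.7%, and the 8-week Vav knockouts between 55.5% and 78.2%.

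The change of the Vav effect between 4 and 8 weeks was tested as an interaction. The effect at 8 weeks was more positive for Ly6c1 by 3.73 (SE 0.432), H1f0 by 3.58 (SE 0.416), Igf2bp3 by 3.24 (SE 0.132), Elfn2 by 2.54 (SE 0.482) and Alox5ap, the activator of leukotriene synthesis, by 1.97 (SE 0.372). It was more negative for Tdrp (-2.77, SE 0.248), Arl5c (-2.71, SE 0.445), Rag2 (-2.71, SE 0.136), BB031773 (-2.67, SE 0.324) and Mir7669 (-2.50, SE 0.344). Of 17 double-positive stage genes 10 were lower, 1 higher and 6 did not pass (12 lower and 1 higher adjusted over the list alone, adjusted p = 2.48e-05, adjusted p = 0.232 with an estimated correlation). Of 22 ribosome biogenesis genes 20 were higher (21 adjusted over the list alone, adjusted p = 2.89e-14, adjusted p = 0.232 with an estimated correlation), as were 8 of 10 mitochondrially encoded genes (9 adjusted over the list alone, adjusted p = 3.71e-07, adjusted p = 0.232 with an estimated correlation). Of 17 genes of the T cell receptor response 7 were lower (9 lower and 1 higher adjusted over the list alone, adjusted p = 0.0167, adjusted p = 0.544 with an estimated correlation), with adjusted p of 0.113, 0.131 and 0.0661 without 8-week control replicate 1, 2 or 3. Of 23 oxidative phosphorylation genes 4 were higher, in the list alone as well (adjusted p = 0.00256, adjusted p = 0.544 with an estimated correlation). Of 15 glycolysis genes 1 was higher and 0 adjusted over the list alone (adjusted p = 0.0325, adjusted p = 0.684 with an estimated correlation), a call lost without any of 6 of the 12 libraries in turn (adjusted p from 0.052 to 0.259). Of 40 cell cycle genes 12 were higher (13 higher and 3 lower adjusted over the list alone), and the list was not called (adjusted p = 0.133), except with a term for sex (adjusted p = 0.00276), without 4-week control replicate 1 (adjusted p = 0.00913) or without 4-week knockout replicate 3 (adjusted p = 0.0241). Of 7 mature T cell genes Gimap3 (-2.04), Gimap6 (-1.61) and Ccr7 (-0.93), named after their values were seen, were lower and 4 did not pass (3 lower and 1 higher adjusted over the list alone, adjusted p = 0.53).

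In limma's test of this interaction, 930 of 10489 genes were higher and 983 lower. Of the 893 autosomal higher calls 134 lay on chromosome 15, Ly6c1 among them, and of the 948 lower ones 7. That chromosome held 4.07% of the tested genes. Its genes had a median change of 0.311, against -0.0286 on the other autosomes. Without it 770 higher and 963 lower were called. Age and table coincide, and at 8 weeks sex coincides with genotype. A term for sex, which only the 4-week libraries could inform, left 569 and 554. Scaling to the same sum made 576 higher and 1244 lower, 31.7% higher in place of 48.6%. Counts were 510 and 504 without 4-week control replicate 2, 535 and 523 without replicate 3, 600 and 639 without 4-week knockout replicate 1, and 646 and 545, and 606 and 535 without 8-week control replicate 1 or 2, and 747 and 626 without 8-week control replicate 3. Of the genes called at 4 weeks, 251 rises and 234 falls were called the same way at 8 weeks, against 36.1 and 30.4 from independent lists (Fisher's exact test, p = 7.11e-164 and p = 5.32e-161), and 0 calls went the opposite way. Across genes the 4-week and 8-week fold changes had r = 0.736 and rho = 0.725.

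The last comparisons took knockout thymocytes after irradiation and transplantation with wild-type competitor cells. Irradiation and transplantation coincide in these mice, so an effect of the competitor cells cannot be isolated. Against control, the transplanted libraries had higher Sdc1, from 0.357 ± 0.0470 (SD, n = 3) to 18.5 ± 2.94 FPKM (SD, n = 4), a log2 change of 3.83, with Ly6c1 at 3.66, Igf2bp3 at 3.64 and Dtx1 at 3.6. The largest falls were BB031773 (-4.17), Car2 (-4.06), Dhrs3 (-3.63) and Arl5c (-3.6). Of 12 Notch pathway and target genes 5 rose and 7 did not pass (9 adjusted over the list alone), with Notch1 at 2.37, Notch3 at 2.21 and Myc at 2.57 (adjusted p = 0.000597, adjusted p = 0.282 with an estimated correlation). Of 17 double-positive stage genes 4 fell and 13 did not pass (10 fell and 2 rose adjusted over the list alone), namely Rag2 (-3.28), Plxnd1 (-2.98), Dntt (-1.66) and Rag1 (-1.54) (adjusted p = 0.00025, adjusted p = 0.441 with an estimated correlation). Of 22 ribosome biogenesis genes 4 rose (9 adjusted over the list alone), Polr1b (1.47), Bop1 (1.02), Ppan (0.93) and Nop56 (0.47) (adjusted p = 4.45e-07, adjusted p = 0.488 with an estimated correlation), and of 10 mitochondrially encoded genes 7 (10 adjusted over the list alone, adjusted p = 3.67e-09, adjusted p = 0.282 with an estimated correlation).

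Gzma (3.0) and Il2rb (1.9) of 6 innate-like genes rose (4 adjusted over the list alone, adjusted p = 0.0165, adjusted p = 0.389 with an estimated correlation). That call was lost without transplanted replicate 1, 3 or 4 (adjusted p = 0.121, 0.173 and 0.187) and with a term for sex (adjusted p = 0.187). Tcrg-C1 (4.82) of 4 gamma-delta genes rose, in the list alone as well (adjusted p = 0.0377, adjusted p = 0.431 with an estimated correlation), and that call was lost without transplanted replicate 1 or 3 (adjusted p = 0.0869 and 0.114). Cd79b (-2.28) and Ighm (-0.81) of 3 B cell markers fell, in the list alone as well (adjusted p = 0.0262, adjusted p = 0.282 with an estimated correlation, and adjusted p = 0.0771 without transplanted replicate 3). Of 40 cell cycle genes only Cenpf (-1.14) fell (0 adjusted over the list alone, adjusted p = 0.0498, adjusted p = 0.808 with an estimated correlation), the call was lost with array weights (adjusted p = 0.716) or a term for sex (adjusted p = 0.954), and the direction turned without transplanted replicate 3 (adjusted p = 0.77). The call was also lost without control replicate 1 (adjusted p = 0.0705) or any 8-week knockout library (adjusted p from 0.0554 to 0.0626).

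In limma's test, 534 of 11632 genes were higher and 535 lower than control, with 120 of 514 autosomal rises on chromosome 15 (23.3%), and groups did not overlap at 24.4% of genes against 5.71% by chance. The counts were 2104 and 1710 without transplanted replicate 3, and 128 and 89, 112 and 87, and 146 and 90 without control replicate 1, 2 or 3. The fit of those groups alone gave 273 and 279, array weights 1648 and 1435, and a term for sex 1363 and 1183, the last informed only by the transplanted libraries. Scaling to the same sum moved the median of all genes to -0.12. With the untransplanted knockout against the same controls, 356 rises and 356 falls were shared, against 24.8 and 23.8 from independent lists. The fold changes had r = 0.874, where unchanged groups against shared controls gave 0.537 in simulation, and a covariance of 0.406 against a simulated 0.0563. The 3 controls cannot be split into sets of at least 2 libraries, so part of the excess may come from the shared controls.

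Between transplanted and untransplanted knockouts no gene passed limma's test in either direction of 11632, with 681 genes at an unadjusted p under 0.05 where 582 would be met by chance. Array weights and robust variances also called 0 genes, with 762 and 665 at that unadjusted p. By Xist and Ddx3y the 3 untransplanted knockouts were male, and the transplanted libraries 2 male (replicates 3 and 4) and 2 female (replicates 1 and 2). A term for sex, which rests on that contrast within the transplanted libraries, left 0 genes called and 2409 at that unadjusted p. There were 1101, 1041 and 1099 without transplanted replicate 1, 2 or 3, 444 without untransplanted replicate 3 and 346 from the fit of those groups alone. The calls were 2 higher and 3 lower without transplanted replicate 2, 0 and 1 without replicate 4, and 0 and 3 without the filter on low values. Tcf3 differed by -0.16 (adjusted p = 0.886). The smallest p went with higher Tnfsf14 (1.19, SE 0.175), Evc (1.95, SE 0.291), Pld4 (1.27, SE 0.196), Edaradd (0.99, SE 0.159) and Mex3a (0.74, SE 0.121), and with lower Hist1h1c (-1.85, SE 0.269), Fos (-2.80, SE 0.415), Mblac1 (-0.89, SE 0.173), Dusp1 (-1.19, SE 0.242) and Iqgap1 (-0.53, SE 0.110), at adjusted p from 0.212 to 0.478. In the self-test on simulated data for this comparison, 61 of 100 genes changed by 1 on the log2 scale and 85 of 100 changed by 2 were recovered. Those genes were drawn from the more highly expressed ones, so recovery among lower genes is not known.

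Gene lists did differ with the preset correlation of camera, and none with an estimated one. Of 40 cell cycle genes 0 passed, over all genes or over the list alone, and all 40 fold changes were negative with a median of -0.48 (adjusted p = 8.55e-07, adjusted p = 0.673 with an estimated correlation). Lower too were immediate early and heat shock genes (0 of 10, and 5 adjusted over the list alone, adjusted p = 0.000449, adjusted p = 0.444 with an estimated correlation), oxidative phosphorylation (0 of 23 both ways, adjusted p = 0.00135, adjusted p = 0.673 with an estimated correlation), glycolysis (0 of 16 both ways, adjusted p = 0.0132, adjusted p = 0.673 with an estimated correlation) and ribosome biogenesis (0 of 22 both ways, adjusted p = 0.0103, adjusted p = 0.716 with an estimated correlation). Without transplanted replicate 3 the last turned its direction (adjusted p = 0.583), and the calls for cell cycle (adjusted p = 0.189), oxidative phosphorylation and glycolysis (adjusted p = 0.583 each) were lost, the last also without knockout replicate 2 (adjusted p = 0.578) or transplanted replicate 4 (adjusted p = 0.067). The fit without transplanted replicate 3 also called the double-positive stage (adjusted p = 0.00131), dendritic cell (adjusted p = 0.0118), E protein and Id, and sex-linked lists lower (adjusted p = 0.0461 each). With array weights oxidative phosphorylation (adjusted p = 0.0553), glycolysis (adjusted p = 0.224) and ribosome biogenesis (adjusted p = 0.197) were no longer called. The double-positive stage (adjusted p = 0.00657), E protein and Id (adjusted p = 0.0161), dendritic cell (adjusted p = 0.0363) and sex-linked lists (adjusted p = 0.0455) were called lower and the innate-like list higher (adjusted p = 0.0252). With a term for sex the double-positive stage (adjusted p = 0.0331), mitochondrially encoded (adjusted p = 0.0433), sex-linked (adjusted p = 0.0486) and T cell receptor response lists (adjusted p = 0.0417) were called higher. The double-positive stage and sex-linked lists thus went opposite ways in the fits that called them. Without untransplanted replicate 1 the T cell receptor response (adjusted p = 0.0389), p53 (adjusted p = 0.016), BCL2 (adjusted p = 0.0401) and gamma-delta lists (adjusted p = 0.0343) were called higher. Without untransplanted replicate 3 the E protein and Id list was called lower (adjusted p = 0.0354). Without transplanted replicate 2, the T cell receptor response list was called higher (adjusted p = 2.46e-05), with mature T cell (adjusted p = 0.00432), trafficking (adjusted p = 0.00225) and innate-like genes (adjusted p = 0.00212), and the interferon list lower (adjusted p = 0.00135). The 3 erythroid markers were higher (0 over all genes, 3 adjusted over the list alone, adjusted p = 7.91e-06, adjusted p = 0.0551 with an estimated correlation). The 823 genes that rose at 4 weeks in the Vav knockout had a median of 0.87 in the untransplanted knockout at 8 weeks, and differed after transplantation by a median of -0.13, 548 of them negative (camera p = 0.00717, p = 0.542 with an estimated correlation). Without transplanted replicate 3 their median was 0.03 with a camera p of 0.48 in the other direction, and camera gave 0.236 without untransplanted replicate 3 and 0.066 without transplanted replicate 2. The 641 genes that fell at 4 weeks had a median of 0.02 (p = 0.351, p = 0.766 with an estimated correlation), and p was 0.0433 in the other direction without transplanted replicate 3 and 0.00315 without replicate 1.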

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

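All tests of explanations in this part were chosen after the results were seen, while the tests of the differences between effects were planned. In the transplanted group, the only group of 4 libraries, 75 measures and genes were tested for a library far from the others, and 6 were found. Chance flags about 1 in 20 groups, so 6 of 75 is not far above chance, and the measures are not independent. Edaradd and Mex3a were also named by their p in a comparison that used these libraries. Transplanted replicate 3 had 251 genes at the value of 1 read (936 to 956 in the others), a chromosome 13 median of -0.0613 (0.0155 to 0.0218), Edaradd at 22.7 FPKM (14.67 to 15.19), Mex3a at 30.9 FPKM (26.87 to 27.3) and Tcf3 at 2.32 FPKM (1.206 to 1.307). Transplanted replicate 1 had a chromosome 8 median of 0.417 (-0.036 to 0.00827).

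The Vav and Lck effects at 4 weeks differed by an interaction in 174 genes one way and 174 the other, among genes that passed the filter in both tables. The largest were Mir7211 (3.32), Foxb1 (2.48), Il2ra (2.3), Itgb7 (2.12) and Phlda1 (2.03) toward a higher Vav effect, and H1fx (-2.67), Fgf13 (-2.22), Mir378b (-2.07), Cd79b (-2.04) and Laptm4b (-1.91) toward a lower one. The Vav effect was higher in the Notch (adjusted p = 0.00322), mature T cell (adjusted p = 1.92e-07), ribosome biogenesis (adjusted p = 2.87e-12), interferon (adjusted p = 5.67e-11), oxidative phosphorylation (adjusted p = 0.0336), trafficking (adjusted p = 0.0113), innate-like (adjusted p = 0.000156) and mitochondrially encoded lists (adjusted p = 0.0113). It was lower in the double-positive stage (adjusted p = 0.0336) and cell cycle lists (adjusted p = 0.0039). With an estimated correlation the interferon and mature T cell lists passed and the other 8 did not. The trafficking call was lost without chromosome 15 (adjusted p = 0.122), and the oxidative phosphorylation, mitochondrial, double-positive stage and cell cycle calls were each lost without at least 1 library.

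The Vav effect at 8 weeks differed from that at 4 weeks by an interaction in 930 genes one way and 983 the other. It was higher for Ly6c1 (3.73), H1f0 (3.58), Igf2bp3 (3.24), Elfn2 (2.54) and Alox5ap (1.97), and lower for Tdrp (-2.77), Arl5c (-2.71), Rag2 (-2.71), BB031773 (-2.67) and Mir7669 (-2.5). The lists that differed were ribosome biogenesis (adjusted p = 2.89e-14), mitochondrially encoded genes (adjusted p = 3.71e-07), oxidative phosphorylation (adjusted p = 0.00256) and glycolysis (adjusted p = 0.0325), all higher, and double-positive stage (adjusted p = 2.48e-05) and T cell receptor response (adjusted p = 0.0167), both lower. None of these 6 passed with an estimated correlation in camera.

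Genes of chromosome 15 were higher in all 10 Vav knockout libraries. A few strongly changed genes are argued against, since 87.2% of the chromosome's tested genes lay above the median of the other autosomes at 8 weeks. Gene length, GC content and expression level are argued against as the whole cause: after subtracting genes of other chromosomes matched on all 3, the shift was 0.595 (95% interval 0.539 to 0.634) beside 0.571 before. An extra copy of the chromosome is a candidate explanation. Of 11 windows of 10 Mb 10 lay above 0, which adds little, since most of the chromosome's genes already did. If RNA followed copy number, 1 extra copy in every cell would give a log2 difference of 0.585. The lowest and highest windows, at -0.479 and 1.01, held only 7 and 8 genes. The other windows lay on either side of 0.585, from 0.48 to 0.736, and the 3 libraries at 8 weeks had 0.707, 0.559 and 0.645. The size therefore does not show in what share of the cells a copy would be present. The extra copy stays a hypothesis, since no DNA was analysed here.

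Few beta variable segments made up most of their signal in the Vav knockout libraries at 8 weeks. Low library complexity is argued against, since the lowest of these libraries held 17337 genes above 0 and the controls 16458 to 17635. Reads shared between related segments are argued against as the whole cause, because 3 different segments led in the 3 libraries. Expanded clones may account for part of it: in 3 of 3 libraries the effective numbers of beta joining segments (3.06, 3.0 and 9.37) and of alpha variable segments (20.1, 5.11 and 2.45) were below those of every 8-week control (at least 12.1 and 39.6). Other values do not go with it in every library: the beta joining number of knockout replicate 3 lay within the 9.04 to 9.65 of the 4-week Vav controls, which come from another table, and alpha joining segments had 26.4, 37.6 and 20.1 in the knockouts and 30.0, 33.3 and 36.1 in the 8-week controls, so replicate 2 was above them. Clones were not sequenced singly, so this stays a hypothesis.

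The 8-week Vav controls were female and the knockouts male by Xist and Ddx3y. Sex as the whole cause of the 1020 autosomal calls is argued against, as far as other groups can stand in for these mice. The measure was the male minus female difference of these genes, signed by the 8-week direction. In the 4-week groups that held both sexes it had a median of -0.0572, where the 8-week change had 1.05. Those groups held 1 or 2 libraries of each sex, and a sex effect that appears only by 8 weeks was not measured there. In the 8-week transplanted libraries, 2 male and 2 female, the median was -0.224, with replicate 3, flagged above for several measures, among the males. An effect of the deletion may account for most of the direction of these calls. The 4-week Vav effect, with 1 male and 2 females in each group, had a median of 0.4 in that direction, with 90.4% of the genes sharing it. A part that sex adds to single genes at 8 weeks stays open.

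Other splits of the libraries show how far chance can be excluded. For the Vav effect at 4 weeks 1 of 10 splits, the real one, called 1484 genes and the highest other 1. For the Lck effect 1 of 10 called 110 (highest other 3), and for the Vav effect at 8 weeks 1 of 10 called 1059 (highest other 0). These 10 splits are too few for a share under 0.05. Chance was not excluded for transplanted against control, where 2 of 35 splits called as many. The real split called 1069 genes and the highest other 3059. That other split put transplanted replicate 3 with the 3 controls, which points to a structure of the samples. It kept the controls whole and so carried much of their difference, and it is no measure of chance. Splits that broke up the controls called 0 genes, but they add that difference to the spread. These 35 splits therefore decide nothing. For the remaining comparisons the splits decide nothing either. Transplanted against untransplanted knockouts had 35 of 35 splits with as many calls as the real 0 (highest other 4), as a real count of 0 must. The Vav and Lck difference had 8 of 100 (348, highest other 955), and the change with age 9 of 100 (1913, highest other 5539, where exchanging control and knockout at one age adds the effects). The other 7 and 8 of these splits kept the true groups of a table whole and so carried its effect. Splits that broke up both tables called at most 1 gene in either comparison, but they add the effects to the spread, so they exclude nothing.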

How the results depend on the processing

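Alternatives with sex, chromosome 15, chromosomes X and Y or receptor segments were chosen after the data were seen, as were those for the 4-week genes after transplantation, and the others were planned. No scaling turned the direction of a list that was called. Among the named genes, 2379 results kept direction and call with other settings and 185 lost the call, and with 1 library left out 1098 kept it, 345 lost it and 2 gained it, with 0 reversed. Among lists, 2110 results kept both with other settings, 100 lost the call, 44 gained one and 4 reversed, and with 1 library left out the numbers were 1286, 38, 42 and 2. The cause was not tested unless fewer genes or libraries entered by construction. The planned count tests were not run because the values are FPKM, and the shallowest library, Lck knockout replicate 2, had 5.49 M reads.

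Lists called with an estimated correlation fell to 0 from 10 (Vav, 4 weeks), 5 (Lck), 8 (Vav, 8 weeks), 6 (transplanted against knockout, 1 with fry), 8 (transplanted against control) and 6 (change with age), and to 2 from 10 for the difference of Vav and Lck. Reversed results were thymic stroma at 4 weeks with fry (0.00604), and for transplanted against knockout with a term for sex the double-positive stage (0.0331), mitochondrially encoded (0.0433) and sex-linked lists (0.0486). Without transplanted replicate 3, ribosome biogenesis against knockout (0.583) and cell cycle against control (0.77) reversed, within left-out ranges of 8.76e-06 to 0.583 and 0.00484 to 0.77. With array weights, lists that lost the call were oxidative phosphorylation (0.0553), glycolysis (0.224) and ribosome biogenesis (0.197) for transplanted against knockout, cell cycle (0.716) and gamma-delta genes (0.0527) for transplanted against control, and double-positive stage (0.057) and oxidative phosphorylation (0.16) for the difference of Vav and Lck. Lists that gained it were T cell receptor response (0.0436, lower) and oxidative phosphorylation (0.0222, higher) in transplanted against control, glycolysis (0.0409, lower) in the difference of Vav and Lck, and interferon (0.038, lower) and leukaemia genes (0.0482, higher) in the change with age. With a term for sex, oxidative phosphorylation was called higher in transplanted against control (0.00584). Lists were not tested with robust variances, which camera does not offer.

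With a mean of 5 FPKM or more, which tests fewer genes, the calls were 537 higher and 390 lower (Vav, 4 weeks), 352 and 301 (Vav, 8 weeks), 296 and 279 (transplanted against control) and 86 lower (difference of Vav and Lck). Without a filter they were 7 and 56 (Lck), 328 higher (Vav, 8 weeks) and 3 lower (transplanted against knockout). Median-of-ratios scaling gave 13 higher for Lck, and scaling to the same sum 5 higher for Lck and 576 higher for the change with age. Array weights gave 1045 lower (Vav, 4 weeks), 2879 and 2886 (Vav, 8 weeks), 1648 and 1435 (transplanted against control), 355 and 397 (difference of Vav and Lck) and 1480 lower (change with age). Fits of the compared groups alone gave 2511 and 2494 (Vav, 8 weeks) and 273 and 279 (transplanted against control). Without chromosome 15 there were 353 higher (Vav, 8 weeks) and 102 higher (difference of Vav and Lck). A term for sex gave 1 and 25 (Lck), 1545 and 1294 (Vav, 8 weeks), 1363 and 1183 (transplanted against control) and 569 and 554 (change with age). For Lck the term rested on 1 female library. For the fits of the 8-week table it rested on the transplanted libraries, with replicate 3 among the males.

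The replicate numbers were tried as a block. The counts were 501 and 393 (Vav, 4 weeks), 0 and 4 (Lck), 288 and 280 (Vav, 8 weeks), 287 and 281 (transplanted against control), 75 and 73 (difference of Vav and Lck) and 591 and 587 (change with age). The labels do not say that the numbers pair libraries, and no comparison had every same-numbered correlation over 0.1: they were -0.109 to 0.0696 (Vav, 4 weeks), -0.0139 to 0.181 (Lck) and 0.0428 to 0.0558 (Vav, 8 weeks, where all 3 correlated best with their own number).

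Overlaps among calls of a log2 change of 1 or more were 0 higher and 7 lower (Vav and Lck), 52 and 68 (Vav at both ages), 58 and 71 (Vav at 4 weeks and transplanted), 0 and 5 (Lck and Vav at 8 weeks) and 165 and 198 (Vav at 8 weeks and transplanted). For the genes higher at 4 weeks, the difference after transplantation had p = 0.542 with an estimated correlation and 0.544 with fry, and with 4-week calls of a log2 change of 1 or more it reversed (0.183).

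With each library left out in turn, the counts higher and lower ranged from 303 to 765 and 187 to 795 (Vav, 4 weeks), 0 to 11 and 2 to 72 (Lck), 76 to 1903 and 66 to 1632 (Vav, 8 weeks), 0 to 2 and 0 to 3 (transplanted against knockout), 112 to 2104 and 87 to 1710 (transplanted against control), 75 to 224 and 53 to 265 (difference of Vav and Lck) and 510 to 1021 and 504 to 1158 (change with age). The p for the 4-week genes after transplantation ranged from 2.06e-07 to 0.48 for the higher and from 0.00315 to 0.955 for the lower ones, reversed at 0.48 and 0.0433 without transplanted replicate 3. The lower genes, not called in the main fit, also turned direction without untransplanted replicate 3 (0.955) and with 4-week calls of a log2 change of 1 or more (0.335).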

Other observations

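The ribosomal protein and GIMAP lists and the tests in this part were chosen after the results were seen, and the shared-call counts were planned. Ribosomal protein genes were higher in the Vav knockout at 4 weeks: 29 of 77 passed in limma's test over all genes and 50 adjusted over the list alone, all 77 fold changes were positive and their median was 0.32 (camera p = 6.02e-20, p = 0.166 with an estimated correlation). In the Lck knockout 1 of 77 passed (15 adjusted over the list alone), 76 fold changes were positive and their median was 0.16 (camera p = 1.75e-18, p = 0.13 with an estimated correlation). The Vav effect was higher than the Lck effect in 2 of 77 (6 adjusted over the list alone), with a median difference of 0.182 (camera p = 5.34e-11, p = 0.234 with an estimated correlation). At 8 weeks 7 of 78 passed in the Vav knockout and 65 adjusted over the list alone, with a median of 1.03 (camera p = 2.63e-20, p = 0.189 with an estimated correlation). The Vav effect on 70 of 77 was higher at 8 than at 4 weeks, with a median difference of 0.68 (camera p = 1.25e-36, p = 0.0398 with an estimated correlation). After transplantation 2 of 78 passed against control (1 adjusted over the list alone), with a median of 0.632 (camera p = 6.88e-13, p = 0.295 with an estimated correlation). Against the untransplanted knockout 0 of 78 passed, and all fold changes were negative with a median of -0.351 (camera p = 1.18e-10, p = 0.344 with an estimated correlation). By share of all FPKM, ribosomal protein genes made up 6.11% in transplanted replicate 3 and between 10.8% and 14.4% in the other transplanted libraries. The 8-week controls had between 6.93% and 7.07%.

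The Vav effect on GIMAP genes, a cluster of GTPases of lymphocyte survival, was lower at 8 than at 4 weeks. At 4 weeks 3 of 8 rose in the Vav knockout, Gimap3 by 1.68, Gimap4 by 1.19 and Gimap5 by 0.38 (camera p = 0.0124, p = 0.256 with an estimated correlation). At 8 weeks 0 rose and 1 fell, in the list alone as well, with a median of -0.746 (camera p = 0.0265, p = 0.338 with an estimated correlation). The change of the Vav effect to 8 weeks was lower in 7 of 8, in the list alone as well, with a median of -1.16 (camera p = 4.98e-06, p = 0.071 with an estimated correlation).

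The 4-week Vav effect recurred in the 8-week libraries with slopes of 1.38, 1.16 and 1.46 in the knockouts and 1.7, 1.34, 1.0 and 1.31 after transplantation, over 1464 genes. Of the genes called in the Lck knockout, 10 rises and 34 falls were also called in the Vav knockout at 8 weeks, where 0.874 and 3.98 would be shared by independent lists. With transplanted against control, 228 rises and 255 falls of the 4-week Vav knockout were shared, where 34.2 and 31.1 would be.

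The distal alpha variable segments held 42.2%, 39.6% and 41.2% of the alpha variable signal in the 4-week Vav controls and 32.8%, 29.8% and 34.4% in the Vav knockouts of that age. They held 40.4%, 41.2% and 41.1% in the Lck controls and 36.7%, 41.6% and 37.3% in the Lck knockouts. At 8 weeks they held 41.9%, 40.2% and 41.3% in the controls, 34.0%, 24.9% and 11.7% in the Vav knockouts, and 47.4%, 28.9%, 28.3% and 25.5% after transplantation, with transplanted replicate 1 above every control. Single segments weighed on these shares: Trav13-2 took 63.5% in Vav knockout replicate 3, Trav21-dv12 42.3% in replicate 2 and Trav8d-2 21.4% in transplanted replicate 1. Proximal segments fell as well. In the 8-week Vav knockout 19 of 26 distal and 17 of 34 proximal segments tested were called lower, with median log2 changes of -1.7 and -1.41.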
